A study of Mus musculus with 11 samples.

How the data were processed

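Nuclei from the mouse hippocampus were profiled by single-nucleus RNA sequencing in 11 samples: 3 of wild-type (WT) and 3 of APP23 genotype at 6 months, and 2 of WT and 3 of APP23 genotype at 24 months. APP23 is a transgenic line that carries human APP, the amyloid precursor protein gene, under a Thy1 promoter cassette active in neurons. The labels' protocols describe nuclei stained for NeuN and DAPI, sorted by flow cytometry, and reverse transcribed with barcoded oligo-dT primers that hold molecular identifiers, with capture of the 3′ ends. The labels do not state that replicates of a group are separate animals, so the p-values given here measure the spread between these samples and no more.

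The deposited matrix holds counts per gene and nucleus, for 28693 genes and 3280 nuclei. All 94113040 values were whole numbers, and 12.7% were above 0. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.12, HTSeq 0.6.0 and the mm10 genome. They give neither the role of each tool nor any filter. Whether the counts are molecules or reads is not stated in these notes, so they are called counts throughout, and intervals cover counting error only. Names of nuclei carry their sample and library, which placed the nuclei in 36 libraries, 1 to 5 per sample; 0 columns of per-sample values stayed unmapped. Total counts per sample ran from 2440735 to 23225581. The genotype label of 24-month APP23 replicate 3 reads APP24 while its title reads APP23, and it was taken as APP23, with 618 counts of human APP. A row named APP, in capitals beside the mouse row App, was taken as the human transgene. Gene positions come from GENCODE mouse annotation on mm10, matched by name.

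Nuclei with 500 or more detected genes were kept, which removed 0. Counts were scaled to 10000 per nucleus and log-transformed in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). From 2000 variable genes, 30 principal components and 15 neighbours, Leiden clustering (leidenalg 0.10.2, resolution 1, seed 0) gave 15 clusters. A cluster took the name of the cell class with the highest mean marker score if at least 3 of its markers were 2-fold above the other nuclei, 1 of them among the 20 genes with the highest fold, and markers of other classes did not outnumber its own among the first 10. The markers were fixed before the data were examined, and these limits were set with the data at hand. The 5 clusters that missed them stayed unnamed and held 342 nuclei. The clusters were read from the same nuclei that were then tested, so class names and class results are not independent of each other. The 4 classes are also tested in the same samples and are not independent of one another.

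Raw counts were summed per sample and class, and a sample entered a class with 10 or more of its nuclei. In interneuron-like nuclei 1 sample, 24-month APP23 replicate 3 with 8 nuclei, stayed out. Each class was fitted with edgeR 4.0.16 in R 4.3.3: TMM factors, the filterByExpr filter by group, and quasi-likelihood tests in 1 model with a mean for each of the 4 groups. This left 13273 dentate granule-like, 13686 CA1-like, 12442 CA2 or CA3-like and 11941 interneuron-like genes. Each class was tested for APP23 against WT at each age, 24 against 6 months in each genotype, the difference of the APP23 effect between the ages, and 24-month APP23 against 6-month WT. The last contrast joins age and genotype and is there because the series description sets these groups beside each other. Benjamini-Hochberg adjusted p-values under 0.05 were called within each class and contrast. Standard errors were taken as the size of the log2 fold change over the square root of the F statistic. CPM beside a test are TMM-scaled, while CPM of human APP are scaled to the summed counts alone. Values after ± are SD between samples.

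Gene lists of pathways and of cell type markers, 35 in all, were fixed together with the markers and tested with camera in limma 3.58.1, with a preset correlation of 0.01. Their p-values were adjusted over all 792 tests. Each test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. Members of a list were also adjusted over the list alone. Shares of nuclei per class and depth per nucleus were compared with exact permutation tests (two-sided, scipy 1.17.1) on 1 value per sample.

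Genes were named by a rule fixed at the same time as the lists. Named were those past the threshold whose samples did not overlap between the groups, without predicted genes and cell type markers, up to 10 in each direction in the class with the most calls and up to 5 in the others. App and Thy1 were named in every class and contrast. For each called list up to 4 members were taken by the largest fold among those that passed, or else by the smallest p. Not all of these members are described. Tnrc6b in dentate granule-like nuclei falls outside the rule for APP23 against WT at 6 months, as its samples overlapped. In that comparison it was named after its values were seen.

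The tests were checked on simulated data made from these counts, with genes changed 2-fold, 4-fold and 8-fold. The changed genes were picked from those above the median count, and each gene was drawn on its own. Recovery of genes with lower counts was not measured. Over 20 simulated comparisons, 112 of 2208 called genes, or 5.07%, were unchanged ones, and the highest share in a single comparison was 10.6%, in CA1-like nuclei of WT. The acceptance limit had first been set per comparison and was changed to the pooled share after that value was seen. In the simulated 6-month genotype comparison, the share of changed genes recovered in CA1-like nuclei was 16.4% at 2-fold, 74.6% at 4-fold and 95.5% at 8-fold, and in interneuron-like nuclei 2.99%, 35.8% and 65.2%.

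The alternatives tried were RLE factors, no filter on low counts, DESeq2 1.42.0, a minimum of 2000 genes per nucleus, Leiden resolution 2, removal of Scrublet doublets, a replicate block, and leaving out each sample in turn. Alternatives added after seeing the data left out libraries that stood apart, or put the sex read from the counts into the model with library 3 of 6-month APP23 replicate 1, whose counts differ in sex from the rest of its sample, left out. Figures were drawn with matplotlib 3.10.9.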

Results

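Counts of 28693 genes in hippocampal nuclei were compared between WT and APP23 samples at 6 and 24 months. The 6-month groups held 951 WT nuclei in 3 samples and 841 APP23 nuclei in 3 samples, and the 24-month groups 655 WT nuclei in 2 samples and 833 APP23 nuclei in 3 samples. Total counts per sample were 9479006 to 14107081 in 6-month WT, 10153200 to 23225581 in 6-month APP23, 7972682 to 11088124 in 24-month WT and 2440735 to 11404210 in 24-month APP23. The lowest total belonged to 24-month APP23 replicate 3, which had 1 library and 93 nuclei. A nucleus held 4024 to 387702 counts over 1237 to 9122 genes. The median count per nucleus was 21797 ± 1903 (SD, n = 5) at 24 months and 33224 ± 10965 (SD, n = 6) at 6 months (exact permutation test, two-sided, p = 0.0433, adjusted 0.173 over 4 tests). It was 29009 ± 11468 (SD, n = 6) in APP23 and 26854 ± 8683 (SD, n = 5) in WT (exact p = 0.749). Counts of Y-linked genes and of Xist, the long RNA of the inactive X chromosome, differed between samples of a group. Those of 6-month WT replicate 3, 6-month APP23 replicate 1 and 24-month APP23 replicates 2 and 3 were male in these counts, and both 24-month WT samples were female. Within 6-month APP23 replicate 1, libraries 1 and 2 had 1057 and 926 CPM of Y-linked genes, and library 3 had 3.25 CPM with 901 CPM of Xist. Ttr, the transthyretin transcript abundant in the choroid plexus, was low in 5 libraries, at 0.824 to 14.2 CPM in the 3 libraries of 6-month WT replicate 1 and at 1.30 and 4.24 CPM in libraries 1 and 2 of 6-month APP23 replicate 1.

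Most nuclei were excitatory neurons of the dentate gyrus and of the CA fields. Dentate granule-like nuclei, which carried Prox1 and C1ql2, made up 32.6% of all nuclei (1068), CA1-like nuclei with Fibcd1 and Mpped1 24.8% (815), CA2 or CA3-like nuclei with Cpne4 and Grik4 10.8% (354), and interneuron-like nuclei with Gad1 and Gad2, which encode the enzymes that make GABA, 8.75% (287). A further 12.6% (414) carried Tshz2 and Slc17a6 and were subicular or cortical-like, and 10.4% (342) stayed unnamed. At Leiden resolution 2 a cluster of 63 nuclei with Calb2, Csf2rb2 and Ajap1 took the name mossy cell. Csf2rb2 and Pdlim5 were among the genes with the highest fold both there and in the CA2 or CA3-like cluster. The clusters named CA2 or CA3-like held 141 and 150 nuclei at resolution 2, against 354 in the class at resolution 1. The CA2 or CA3-like class may therefore hold these 63 mossy cell nuclei, and its results below include them if so. Dentate granule-like nuclei made up 37.9% ± 10.05 (SD, n = 6) of an APP23 sample and 28.5% ± 9.09 (SD, n = 5) of a WT sample (exact permutation test, two-sided, p = 0.139). The corresponding shares were 22.6% ± 6.30 and 25.4% ± 4.42 for CA1-like nuclei (exact p = 0.420), 9.96% ± 3.29 and 12.3% ± 1.42 for CA2 or CA3-like nuclei (exact p = 0.175). They were 8.87% ± 1.18 and 8.83% ± 1.78 for interneuron-like nuclei (exact p = 0.963), and 12.4% ± 3.72 and 12.2% ± 4.23 for subicular or cortical-like nuclei (exact p = 0.935). Between the ages, the exact p was 0.805, 0.543, 0.411, 0.526 and 0.649 for the classes in the same order. No adjusted p of these 10 tests was under 0.877, and the sort on NeuN, a neuronal nuclear protein, can set such shares. Inside the dentate granule-like class, 59.9% of 24-month WT nuclei fell in cluster 1, while 55.3% to 60.5% of the nuclei of the other groups fell in cluster 0. Inside the CA1-like class, cluster 3 held 55.3% of 24-month WT and 50.7% of 24-month APP23 nuclei, and cluster 5 held 56.0% of 6-month WT and 60.2% of 6-month APP23 nuclei.

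The transgene was counted in every neuronal class of all APP23 samples that entered it. Human APP, which encodes the precursor of the amyloid-beta peptide, reached 297 ± 35.9 CPM (SD, n = 3) in dentate granule-like nuclei at 6 months and 403 ± 90.1 CPM (n = 3) at 24 months. In CA1-like nuclei it reached 304 ± 62.3 and 539 ± 242 CPM (n = 3 each), in CA2 or CA3-like nuclei 161 ± 85.0 and 318 ± 101 CPM (n = 3 each). In interneuron-like nuclei it reached 101 ± 36.4 CPM (n = 3) and 178 ± 95.8 CPM (n = 2). WT samples had 0 counts of it apart from 1 count in dentate granule-like nuclei of 24-month replicate 1. Against a floor of 3 counts over the summed WT group, human APP at 6 months was at least 767-fold higher in dentate granule-like, 1003-fold in CA1-like, 327-fold in CA2 or CA3-like and 106-fold in interneuron-like nuclei. At 24 months it was at least 846-fold higher in CA1-like, 388-fold in CA2 or CA3-like and 105-fold in interneuron-like nuclei. The ratio in dentate granule-like nuclei, against the single WT count, was 1717 (95% counting interval 308 to 67856). Within APP23 samples, CA1-like nuclei had more human APP than CA2 or CA3-like nuclei in 6 of 6 samples, by a mean log2 ratio of 0.90 ± 0.86 (SD; exact p = 0.03125, the smallest these samples allow, adjusted 0.125 over 20 tests). They had more than interneuron-like nuclei in 5 of 5 samples, by 1.76 ± 0.32 (SD; exact p = 0.0625, the smallest possible, adjusted 0.125). Whether part of the human APP counted in a class came from RNA of other cells was not tested. Ttr, abundant in the choroid plexus, reached up to 472 CPM in a library of these sorted nuclei.

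**Figure D1:**
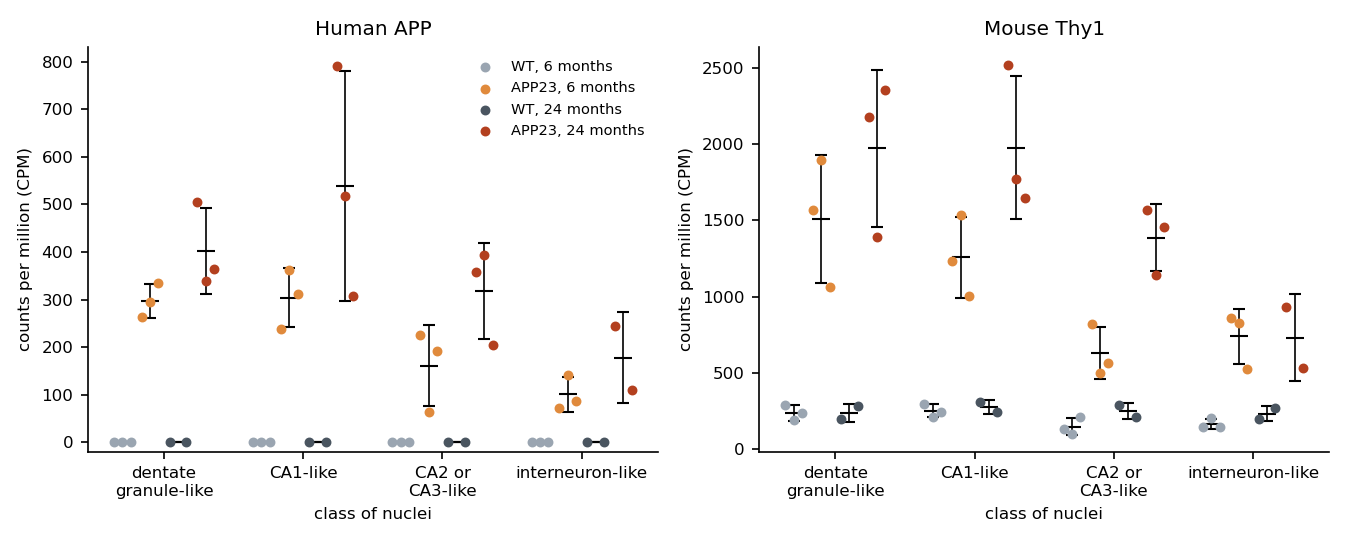
CPM of human APP (one panel) and the mouse Thy1 row (the other) in each sample, by cell class and group, with points for samples and bars for mean and SD. The Thy1 row may include counts from Thy1 sequence in the transgene cassette. Human APP was 0 in all WT points but one, with 1 count, and lay between 64.4 CPM, in CA2 or CA3-like nuclei, and 791 CPM, in CA1-like nuclei, in APP23 samples of the 4 tested classes.

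The genotypes were compared within each age, first at 6 months, for the effect of the transgene. Thy1, a cell-surface glycoprotein of neurons whose promoter drives the transgene (ENSMUSG00000032011, mm10 chromosome 9, 44043384 to 44048579), rose in APP23 in each of the 4 classes. It rose 6.04-fold in dentate granule-like nuclei, from 244 ± 59.7 to 1469 ± 408 CPM (SD, n = 3 each; log2 fold change 2.59, SE 0.23, adjusted p = 3.70e-08). It rose 4.88-fold in CA1-like nuclei, to 1231 ± 269 CPM from 252 ± 37.0 CPM (2.29, SE 0.21, adjusted p = 2.30e-07), 4.09-fold in CA2 or CA3-like nuclei (2.03, SE 0.27, adjusted p = 8.07e-05) and 4.28-fold in interneuron-like nuclei (2.10, SE 0.30, adjusted p = 0.00117). Without the 5 libraries low in Ttr, the interneuron-like change was 1.92 with adjusted p = 0.135. Thy1 counts, here and below, may come from the mouse gene or from Thy1 sequence in the transgene cassette. These data cannot tell the sources apart, so a rise of the mouse gene itself is not shown. Mouse App (ENSMUSG00000022892, chromosome 16, 84949685 to 85173766) did not pass in any class, at −0.14 (SE 0.20) in dentate granule-like, −0.38 (SE 0.20) in CA1-like, −0.13 (SE 0.26) in CA2 or CA3-like and 0.02 (SE 0.23) in interneuron-like nuclei.

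In CA1-like nuclei at 6 months 20 of 22 measured cholesterol synthesis genes had higher estimates in APP23, with a median log2 fold change of 0.65 (camera adjusted p = 1.06e-05; adjusted p = 0.174 with an estimated correlation). None of the 22 passed over all genes tested, and 2 passed when adjusted over the list alone. These were Msmo1, a sterol demethylase, at 185 ± 36.1 against 99.7 ± 24.0 CPM (SD, n = 3 each; log2 fold change 0.89, SE 0.27), and Mvk, mevalonate kinase, at 29.8 ± 12.8 against 5.98 ± 3.27 CPM (2.31, SE 0.70). The list kept its call without each sample in turn, with adjusted p up to 0.00262. Markers of glia in the same nuclei had median log2 fold changes of −0.05 for oligodendrocytes, −0.48 for astrocytes and −1.55 for microglia, and did not pass. The list did not pass in dentate granule-like (adjusted p = 0.347), CA2 or CA3-like (0.0571) or interneuron-like nuclei (0.108), and whether the classes differ was not tested. Of the 8 lists called at 6 months, 4 kept their call without each sample. They were these cholesterol genes and, in all classes but interneuron-like nuclei, the transgene promoter and product, a call set by the genotype itself. The immediate early genes of dentate granule-like nuclei, which neurons switch on with activity, were among the others: 14 of 18 were lower, with a median of −0.67 (adjusted p = 0.00554; 0.719 with an estimated correlation). That call ended without WT replicate 2 (adjusted p = 0.101) and without WT replicate 3 (0.170).

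By gene, edgeR called 3 genes in dentate granule-like, 3 in CA1-like, 2 in CA2 or CA3-like and 2 in interneuron-like nuclei, with human APP and Thy1 in each, and DESeq2 called 5, 5, 20 and 52. The remaining call in both of the first classes was Tnrc6b, which encodes a scaffold protein of microRNA silencing (ENSMUSG00000047888, chromosome 15, 80711313 to 80941085). It was lower in APP23, at 522 ± 114 against 1790 ± 1181 CPM in dentate granule-like nuclei (SD, n = 3 each; −1.78, SE 0.31, adjusted p = 0.0218) and 452 ± 56.4 against 1237 ± 574 CPM in CA1-like nuclei (−1.45, SE 0.26, adjusted p = 0.0338). The high WT values came from 3 libraries of WT replicates 1 and 2, with 1561 to 3678 CPM over all nuclei, while the other 3 libraries of those replicates had 435 to 559 CPM. Without these 3 libraries the CA1-like change was −0.31 with adjusted p = 0.999.

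**Figure D2:**
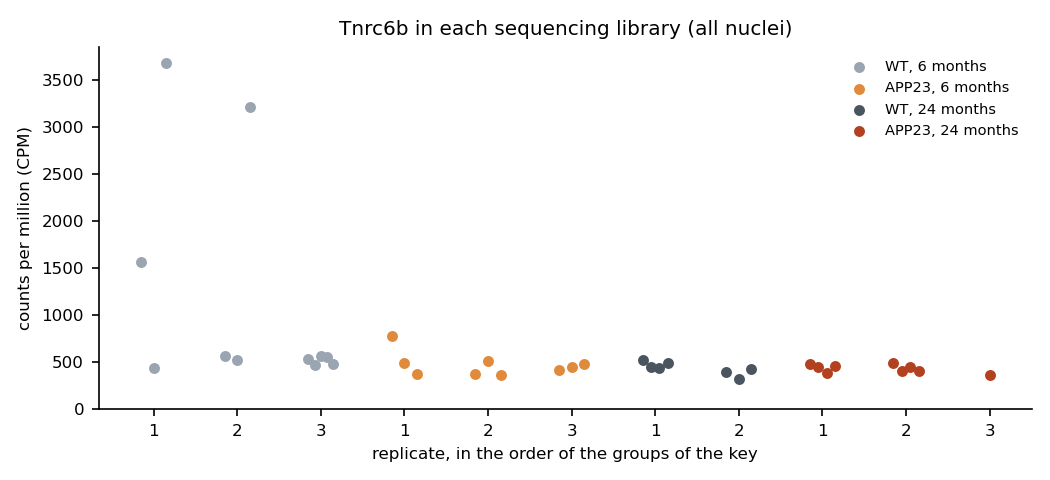
CPM of Tnrc6b in each of the 36 libraries, all nuclei summed, ordered by sample, with 1 point per library. The 3 libraries above 1000 CPM belong to 6-month WT replicates 1 and 2, and the 30 libraries of the 9 other samples lie between 324 and 776 CPM.

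At 24 months Thy1 rose in APP23 as well, 8.24-fold in dentate granule-like nuclei (1976 ± 528 CPM, SD, n = 3, against 241 ± 65.9 CPM, n = 2; log2 fold change 3.04, SE 0.27, adjusted p = 6.99e-08), 7.16-fold in CA1-like nuclei (2.84, SE 0.25, adjusted p = 1.19e-07) and 5.69-fold in CA2 or CA3-like nuclei (2.51, SE 0.32, adjusted p = 3.49e-05). In interneuron-like nuclei it stood at 728 ± 278 against 231 ± 45.9 CPM (n = 2 each; 1.66, SE 0.36) and did not pass in edgeR (adjusted p = 0.391), but passed in DESeq2 (adjusted p = 0.0139). Mouse App did not pass in any class, at −0.20 (SE 0.22) in dentate granule-like, −0.23 (SE 0.22) in CA1-like, 0.45 (SE 0.29) in CA2 or CA3-like and −0.20 (SE 0.29) in interneuron-like nuclei. In edgeR the calls were human APP and Thy1 in the first 3 classes and human APP alone in interneuron-like nuclei. The last call ended without WT replicate 1 (adjusted p = 0.107), WT replicate 2 (0.169) or APP23 replicate 1 (0.0631), each of which left 0 calls there. DESeq2 called 10, 8, 5 and 6 genes in the 4 classes.

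For cholesterol synthesis genes of CA1-like nuclei at 24 months, 19 of 22 estimates were higher in APP23, with a median log2 fold change of 0.94 (camera adjusted p = 2.72e-10; adjusted p = 0.0750 with an estimated correlation). None passed over all genes tested, and 4 passed when adjusted over the list alone. Among these, Msmo1 stood at 355 ± 34.9 (SD, n = 3) against 143 ± 22.9 CPM (n = 2; 1.30, SE 0.31), and Fdft1, squalene synthase, at 78.8 ± 7.74 against 25.3 ± 14.8 CPM (1.64, SE 0.58). Nsdhl, a sterol dehydrogenase, stood at 56.3 ± 33.9 against 10.98 ± 1.34 CPM (2.32, SE 0.81). The call held without each sample in turn, with adjusted p up to 3.73e-06. The glial markers had medians of 0.16 for oligodendrocytes, −0.19 for astrocytes and 2.30 for microglia in these nuclei, and did not pass. In CA2 or CA3-like nuclei 18 of 21 members were higher, with a median of 0.93 (adjusted p = 2.14e-05; 0.266 with an estimated correlation), and that call ended without WT replicate 2 (adjusted p = 0.0788). The list did not pass in dentate granule-like (0.246) or interneuron-like nuclei (0.0664).

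Immediate early genes of dentate granule-like nuclei were lower in 24-month APP23 than in 24-month WT for 16 of 18 members, with a median log2 fold change of −0.92 (camera adjusted p = 4.23e-06; adjusted p = 0.314 with an estimated correlation). None passed over all genes tested, and 3 passed when adjusted over the list alone. Fos, a transcription factor subunit induced by neuronal activity (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), stood at 3.14 ± 2.75 (SD, n = 3) against 88.0 ± 58.2 CPM (n = 2; −4.62, SE 0.97). Arc, an activity-induced synaptic protein (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570), stood at 0.978 ± 1.09 against 33.0 ± 9.88 CPM (−4.83, SE 1.16), and Nr4a1, an inducible nuclear receptor, at 36.3 ± 23.8 against 119 ± 50.7 CPM (−1.69, SE 0.57). The call held without each sample, with adjusted p up to 0.0173. The same list was higher at 24 than at 6 months in WT dentate granule-like nuclei, for 13 of 18 members (median 0.44, adjusted p = 0.0255; 0.757 with an estimated correlation), with Fos at 88.0 ± 58.2 against 15.7 ± 15.7 CPM. That call was lost without 6-month WT replicate 1 (0.296) or 24-month WT replicate 2 (0.623), and Fos in APP23 stood at 1.97 ± 0.994 CPM at 6 and 3.14 ± 2.75 CPM at 24 months. In the same nuclei the medians were −0.24 for oligodendrocyte, 0.16 for astrocyte and 1.01 for microglia markers. The 24-month groups differed in sex, with 0 of 2 WT and 2 of 3 APP23 samples male, and the dentate granule-like nuclei of WT lay mostly in another cluster than those of APP23. The sex-linked genes were also called in 3 classes, with the call in CA2 or CA3-like nuclei the one that held without each sample (adjusted p = 3.22e-05; 0.273 with an estimated correlation). Of the 11 lists called at 24 months, 6 held without each sample. Among the 6 was the transgene promoter and product in all classes but interneuron-like nuclei, a call set by the genotype itself.

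**Figure D3:**
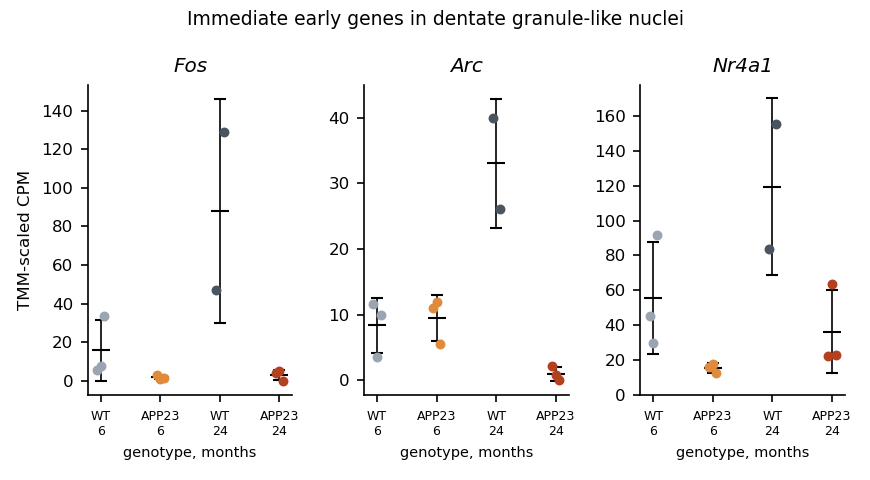
TMM-scaled CPM of Fos, Arc and Nr4a1 in dentate granule-like nuclei of each sample, by group, with points for samples and bars for mean and SD. At 24 months the 3 APP23 samples had means of 3.14, 0.978 and 36.3 CPM and the 2 WT samples 88.0, 33.0 and 119 CPM for the 3 genes in this order.

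Whether the effect of the transgene differed between the ages was tested directly. Thy1 differences of 0.45 in dentate granule-like, 0.55 in CA1-like, 0.48 in CA2 or CA3-like and −0.44 in interneuron-like nuclei did not pass. The same test gave adjusted p = 0.180 for cholesterol synthesis genes in CA1-like nuclei, 0.0526 for immediate early genes in CA1-like nuclei and 0.479 for immediate early genes in dentate granule-like nuclei. No gene was called in any class by edgeR or by DESeq2. At unadjusted p under 0.05, edgeR counted 631 dentate granule-like, 585 CA1-like, 516 CA2 or CA3-like and 535 interneuron-like genes. These were 4.75%, 4.27%, 4.15% and 4.48% of the genes tested, and unchanged genes alone give a share of 0.05. A single gene was called without 6-month WT replicate 3 in dentate granule-like and in CA1-like nuclei, and without 24-month WT replicate 1 in interneuron-like nuclei, and 4 dentate granule-like, 1 CA1-like and 1 CA2 or CA3-like genes were called without the libraries low in Ttr. Both lists called in this test are given with the closer looks.

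Samples of 24 and 6 months were compared within WT for the effect of age. Cholesterol synthesis genes of CA1-like nuclei were higher at 24 months for 17 of 22 members, with a median of 0.52 (camera adjusted p = 0.00255; adjusted p = 0.336 with an estimated correlation), a call that ended without 24-month replicate 1 (adjusted p = 0.184) and without 6-month replicate 3 (0.0716). The members with the smallest p were Hmgcs1, which makes the precursor of mevalonate (1.10, SE 0.51), and Insig1, which holds the sterol sensor in the endoplasmic reticulum (1.36, SE 0.71). Markers of the choroid plexus, Kl and Ttr, were called in the same nuclei (median 1.63, adjusted p = 0.0126; 0.333 with an estimated correlation), a call lost without 6-month replicate 1 (0.0654), 24-month replicate 1 (0.126) or 24-month replicate 2 (0.0759). Thy1 was at −0.02 (SE 0.24) in dentate granule-like, 0.14 (SE 0.22) in CA1-like, 0.74 (SE 0.29) in CA2 or CA3-like and 0.45 (SE 0.32) in interneuron-like nuclei on the log2 scale, 24 against 6 months. Mouse App was at 0.28, 0.33, 0.35 and 0.45 in the same order, and none of the 8 values passed. Cytosolic ribosomal protein genes were called for age in WT as well, in CA1-like and CA2 or CA3-like nuclei. Further calls were oligodendrocyte markers in CA2 or CA3-like and dentate granule-like nuclei. In CA2 or CA3-like nuclei they also covered interferon response and antigen presentation and immediate early genes. In interneuron-like nuclei they covered astrocyte markers and mitochondrially encoded genes. Each of the 11 lists called for age in WT lost its call without at least 1 sample.

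No gene was called for age in WT by edgeR in any class, with 872 dentate granule-like, 489 CA1-like, 420 CA2 or CA3-like and 555 interneuron-like genes at unadjusted p under 0.05. These were 6.57%, 3.57%, 3.38% and 4.65% of the genes tested, where unchanged genes alone give a share of 0.05. DESeq2 called 15, 4, 4 and 4 genes in these classes. Without 6-month replicate 2 edgeR called 2 dentate granule-like genes, and without 6-month replicate 3 it called 1 gene in each of the dentate granule-like, CA1-like and interneuron-like classes.

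The ages were then compared within APP23. In dentate granule-like nuclei 4 genes rose between 6 and 24 months. Meg3, a long noncoding RNA of an imprinted locus (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726), rose from 4074 ± 503 to 6252 ± 1005 CPM (SD, n = 3 each; log2 fold change 0.62, SE 0.11, adjusted p = 0.0188). Snhg11, annotated as protein coding (ENSMUSG00000044349, chromosome 2, 158375638 to 158386145), rose from 2574 ± 290 to 4230 ± 1088 CPM (0.72, SE 0.13, adjusted p = 0.0289). Stxbp2, which encodes a syntaxin-binding protein of vesicle release (ENSMUSG00000004626, chromosome 8, 3630955 to 3643644), rose from 261 ± 28.7 to 694 ± 217 CPM (1.41, SE 0.22, adjusted p = 0.00538). RP23.407N2.2, a transcript named after a genomic clone and not matched by name in the annotation, rose from 185 ± 34.5 to 494 ± 68.9 CPM (1.41, SE 0.22, adjusted p = 0.00538). Of the 4 calls, 1 was left without 6-month replicate 1 and 0 without 6-month replicate 3 or 24-month replicate 3, 10 genes were called without the libraries low in Ttr, and DESeq2 called 19. Meg3 and Snhg11 ended at adjusted p = 0.0720 and 0.104, with log2 fold changes still at 0.62 and 0.72, without the libraries high in Tnrc6b, which are WT libraries that share the estimate of spread. With sex in the model and library 3 of 6-month APP23 replicate 1 left out, Snhg11 ended at 0.106 (log2 fold change 0.73). In the same nuclei and contrast mitochondrially encoded genes were higher for 6 of 7 members (adjusted p = 0.0227; 0.352 with an estimated correlation), a call lost without 6-month replicate 1 (0.0634), 6-month replicate 3 (0.196), 24-month replicate 1 (0.113) or 24-month replicate 2 (0.0979). Microglia markers were higher for 5 of 6 members (adjusted p = 0.00889; 0.276 with an estimated correlation), a call lost without 24-month replicate 1 (0.0538) or 24-month replicate 3 (0.0580).

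In CA1-like nuclei of APP23, 20 of 22 cholesterol synthesis genes had higher estimates at 24 months (median 0.91, camera adjusted p = 3.62e-09; adjusted p = 0.0750 with an estimated correlation). None passed over all genes tested, and 4 passed when adjusted over the list alone. Among these were Msmo1 at 355 ± 34.9 against 185 ± 36.1 CPM (SD, n = 3 each; 0.94, SE 0.27), Acat2, a cytosolic thiolase, at 34.2 ± 21.1 against 6.05 ± 2.75 CPM (2.52, SE 0.74), and Sqle, squalene epoxidase, at 142 ± 46.3 against 59.3 ± 18.6 CPM (1.25, SE 0.42). In CA2 or CA3-like nuclei all 21 members measured were higher (median 0.78, adjusted p = 0.000194; 0.333 with an estimated correlation), and Msmo1 passed over the list alone (1.32, SE 0.31). Immediate early genes of CA1-like nuclei had 13 of 18 estimates lower and a median of −0.94 (adjusted p = 1.96e-05; 0.703 with an estimated correlation). Among them were Arc at 33.5 ± 31.3 against 145 ± 37.9 CPM (−2.00, SE 0.49) and Fos at 12.4 ± 17.99 against 75.8 ± 37.5 CPM (−2.38, SE 0.71), 2 of the 4 that passed over the list alone. Cytosolic ribosomal protein genes had 65 of 78 lower and a median of −0.49 (adjusted p = 8.47e-08; 0.757 with an estimated correlation). Of these Rps19, a protein of the small ribosomal subunit, passed over the list alone, at 50.5 ± 8.20 against 152 ± 27.6 CPM (−1.59, SE 0.36). All 5 microglia markers measured were higher in the same nuclei (adjusted p = 0.0117; 0.349 with an estimated correlation). These calls held without each sample. The ribosomal list was also called for age in CA1-like nuclei of WT, a call that did not hold without each sample.

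Human APP differed between 24 and 6 months by a log2 fold change of 0.48 (SE 0.26) in dentate granule-like, 0.87 (SE 0.31) in CA1-like, 1.05 (SE 0.41) in CA2 or CA3-like and 0.84 (SE 0.70) in interneuron-like nuclei and passed in none. Thy1 in CA2 or CA3-like nuclei stood at 1415 ± 245 against 609 ± 136 CPM (SD, n = 3 each; 1.21, SE 0.26) and did not pass in edgeR (adjusted p = 0.140), but passed in DESeq2 (0.0133) and without the filter on low counts (0.00150). In the other classes Thy1 was at 0.43 (SE 0.21), 0.69 (SE 0.20) and 0.01 (SE 0.32) and mouse App at 0.23, 0.47 and 0.23, in the order dentate granule-like, CA1-like and interneuron-like. Mouse App in CA2 or CA3-like nuclei, at 0.94 (SE 0.26), did not pass over all genes (adjusted p = 0.526). It passed when adjusted over the list of the transgene promoter and product alone (0.00114), a correction too narrow to count as a call. In edgeR 0 genes were called in CA1-like, CA2 or CA3-like and interneuron-like nuclei, with 917, 763 and 415 at unadjusted p under 0.05, and DESeq2 called 32, 14 and 0. The 917, 763 and 415 genes were 6.70%, 6.13% and 3.48% of those tested, where unchanged genes alone give a share of 0.05. Without 24-month replicate 2 edgeR called 7 CA1-like, 3 CA2 or CA3-like and 1 interneuron-like gene, without 24-month replicate 1 it called 4 CA2 or CA3-like genes, and without 24-month replicate 3 it called 1 CA1-like gene.

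The last contrast set 24-month APP23 beside 6-month WT, as the series description does, and cannot separate age from genotype. In CA1-like nuclei all 22 cholesterol synthesis genes measured were higher in 24-month APP23 (median log2 fold change 1.63, camera adjusted p = 2.94e-25; adjusted p = 0.0228 with an estimated correlation), 2 over all genes tested and 13 when adjusted over the list alone. Msmo1 (ENSMUSG00000031604, chromosome 8, 64718139 to 64733792) rose from 99.7 ± 24.0 to 355 ± 34.9 CPM (SD, n = 3 each; 1.83, SE 0.27, adjusted p = 0.00203). Estimates of cholesterol synthesis genes in CA2 or CA3-like nuclei were higher for 20 of 21, with a median of 1.05 (adjusted p = 1.74e-11; 0.0750 with an estimated correlation). For the same list in dentate granule-like nuclei 18 of 21 were higher, with a median of 0.71 (adjusted p = 0.000223; 0.196 with an estimated correlation). In CA2 or CA3-like nuclei 5 members passed over the list alone, Sqle among them (1.90, SE 0.45), and in dentate granule-like nuclei 0 did. The oligodendrocyte markers moved with them in CA2 or CA3-like nuclei, with 6 of 6 higher and a median of 1.65 (adjusted p = 0.000430; 0.266 with an estimated correlation). Of these, Mbp, a myelin protein, stood at 106 ± 4.93 against 21.1 ± 2.26 CPM (2.32, SE 0.59). Immediate early genes had mostly lower estimates in CA1-like nuclei (12 of 18 lower, median −0.56, adjusted p = 0.000304; 0.719 with an estimated correlation) and in CA2 or CA3-like nuclei (14 of 18 lower, median −1.34, adjusted p = 0.000261; 0.581 with an estimated correlation).

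**Figure D4:**
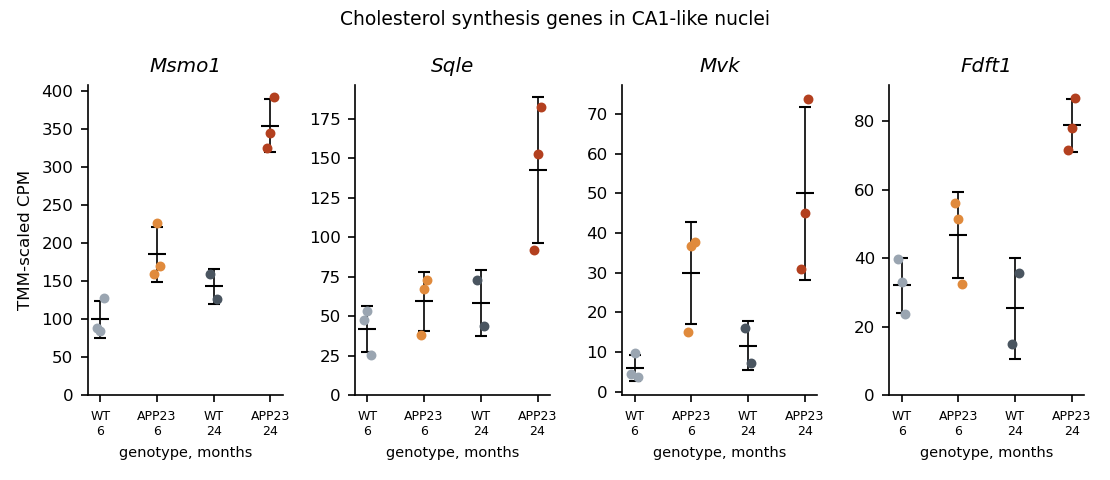
TMM-scaled CPM of Msmo1, Sqle, Mvk and Fdft1 in CA1-like nuclei of each sample, by group, with points for samples and bars for mean and SD. Msmo1 had means of 99.7 CPM in 6-month WT, 185 CPM in 6-month APP23, 143 CPM in 24-month WT and 355 CPM in 24-month APP23.

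Thy1 rose in this contrast by 3.02 (SE 0.23, adjusted p = 1.60e-09) in dentate granule-like, 2.98 (SE 0.21, adjusted p = 1.21e-09) in CA1-like, 3.24 (SE 0.28, adjusted p = 3.66e-09) in CA2 or CA3-like and 2.11 (SE 0.32, adjusted p = 0.00334) in interneuron-like nuclei, the last at 1.64 with adjusted p = 0.237 without 24-month APP23 replicate 1. Human APP was called in all 4 classes. Mouse App was at 0.09, 0.09, 0.80 and 0.25 in the same order and passed in none. In CA2 or CA3-like nuclei it passed when adjusted over the list of the transgene promoter and product alone (0.00416), again too narrow a correction for a call. In CA2 or CA3-like nuclei Eef2k, a kinase that slows protein elongation (ENSMUSG00000035064, chromosome 7, 120842831 to 120907450), rose from 52.3 ± 25.8 to 245 ± 81.8 CPM (SD, n = 3 each; 2.22, SE 0.42). Pxdn, a peroxidase of the extracellular matrix (ENSMUSG00000020674, chromosome 12, 29937608 to 30017658), fell from 285 ± 32.7 to 84.6 ± 5.65 CPM (−1.76, SE 0.33), and both had adjusted p = 0.0248. Msmo1 rose there as well (1.66, SE 0.32, adjusted p = 0.0248). RP23.407N2.2 rose in dentate granule-like nuclei, from 215 ± 37.1 to 494 ± 68.9 CPM (1.20, SE 0.22, adjusted p = 0.0329). Tnrc6b was lower in dentate granule-like (−1.95, SE 0.32, adjusted p = 0.00579) and CA1-like nuclei (−1.47, SE 0.26, adjusted p = 0.0178), and stood at −0.02 (adjusted p = 0.995) and −0.33 (adjusted p = 0.815) without the 3 WT libraries high in it.

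The counts of called genes in this contrast were 4 in dentate granule-like, 5 in CA1-like, 5 in CA2 or CA3-like and 2 in interneuron-like nuclei (23, 27, 13 and 15 in DESeq2), and they depended on single samples. In dentate granule-like nuclei 2 were left without 24-month APP23 replicate 2, and in interneuron-like nuclei 1 was left without 24-month APP23 replicate 1. In CA1-like nuclei the count was 2 without 6-month WT replicate 2, 8 without 24-month APP23 replicate 2 and 3 without 24-month APP23 replicate 3, while in CA2 or CA3-like nuclei it was 2 without 6-month WT replicate 2 or 24-month APP23 replicate 3. Msmo1 in CA1-like nuclei ended at adjusted p = 0.0539 without 6-month WT replicate 2 (log2 fold change 1.72), 0.0741 without the libraries low in Ttr (1.75) and 0.204 without those high in Tnrc6b (1.33). Pxdn ended at 0.0516 to 0.167 without each of the 6 samples in turn, with log2 fold changes of −1.81 to −1.66. It also ended at Leiden resolution 2 (0.117) and without the libraries low in Ttr (0.175). With sex in the model and library 3 of 6-month APP23 replicate 1 left out it ended at 0.0538. Eef2k ended at 0.358, 0.198, 0.296 and 0.119 without 6-month WT replicates 2 and 3 and 24-month APP23 replicates 1 and 3, with 1.94 to 2.23. Msmo1 in CA2 or CA3-like nuclei ended at 0.148, 0.263, 0.107 and 0.592 without the 6-month WT replicates 1, 2 and 3 and 24-month APP23 replicate 3, with 1.41 to 1.70. RP23.407N2.2 ended at 0.298 and 0.192 without 6-month WT replicates 2 and 3 and at 0.0528 to 0.306 without each of the 24-month APP23 replicates, with 1.08 to 1.28. Without the libraries high in Tnrc6b it ended at 0.356, and with sex in the model and library 3 of 6-month APP23 replicate 1 left out at 0.113. Of the 17 lists called, 9 kept their call without each sample, including those of cholesterol, immediate early and oligodendrocyte genes described here. Among the 9 was also the transgene promoter and product in all classes but interneuron-like nuclei, a call set by the genotype itself.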

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

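The gene lists and contrasts were planned, while the tests of explanations, the other splits of the samples and the fits of lists without single samples or with sex in the model were chosen after the results were seen.

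Human APP was also counted in nuclei that no comparison between groups used. In subicular or cortical-like nuclei it stood at 302 ± 60.0 CPM (SD, n = 3) at 6 months and 409 ± 157 CPM (n = 2) at 24 months, at least 365-fold and 305-fold higher than the floor of 3 counts over the WT group. In unnamed nuclei it stood at 133 ± 10.2 and 231 ± 31.9 CPM (n = 2 each), at least 181-fold and 194-fold higher. Among APP23 samples, subicular or cortical-like nuclei had more human APP than interneuron-like nuclei in 5 of 5 samples, with a mean log2 ratio of −1.48 ± 0.52 (SD) for interneuron-like over subicular or cortical-like nuclei (exact p = 0.0625, the smallest possible, adjusted 0.125).

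Both lists that passed the test of a different APP23 effect at 24 and 6 months were short. The 5 microglia markers in CA1-like nuclei were all higher in that difference (adjusted p = 0.0224; 0.416 with an estimated correlation), and the call was lost without 6 of the 11 samples. These were 6-month WT replicates 1 (0.0896) and 3 (0.0985), 6-month APP23 replicate 3 (0.139), 24-month WT replicates 1 (0.238) and 2 (0.692) and 24-month APP23 replicate 2 (0.0796). Sex-linked genes in CA2 or CA3-like nuclei differed as well (adjusted p = 0.00908; 0.588 with an estimated correlation), where the male samples, by Xist and Y-linked counts, were 1 of 3 in both 6-month groups, 0 of 2 in 24-month WT and 2 of 3 in 24-month APP23. That call was lost without 6-month WT replicate 3 (0.377), 24-month WT replicate 1 (0.151) or 24-month WT replicate 2 (0.200). It was also lost with sex in the model and library 3 of 6-month APP23 replicate 1 left out (0.537).

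Cholesterol synthesis genes were higher in APP23 than in WT in CA1-like nuclei at both ages, and an effect of the genotype on these neurons stays open as an untested explanation. The tables argue against RNA from oligodendrocytes or astrocytes at 6 months, as the higher upper quartile of their marker lists, that of astrocytes, was 0.0435 on the log2 scale against a median of 0.65 for the cholesterol genes. Without the libraries low in Ttr the list kept adjusted p = 7.61e-07 at 6 months, which argues against those libraries, although the call itself did not pass with an estimated correlation (0.174). With sex in the model and library 3 of 6-month APP23 replicate 1 left out it kept 1.48e-10 at 24 months, which argues against more male samples in 1 group as the whole cause there, although this call did not pass with an estimated correlation either (0.0750). At 24 months RNA from glia cannot be told apart from a change in the neurons, although the nuclei were sorted on NeuN, since the upper quartile of oligodendrocyte markers, 1.68, lay above the cholesterol median of 0.94.

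Immediate early genes were lower in APP23 dentate granule-like nuclei at 24 months. With sex in the model and library 3 of 6-month APP23 replicate 1 left out the list kept adjusted p = 3.68e-05, which argues against more male samples in 1 group as the whole cause, although the call did not pass with an estimated correlation (0.314). The same genes were lower past the threshold in 2 of 4 classes and higher past it in none, with the call in CA1-like nuclei (adjusted p = 0.0434; 0.907 with an estimated correlation) lost without 24-month WT replicate 1 (0.848), 24-month APP23 replicate 1 (0.239) or replicate 3 (0.115), and without the filter on low counts (0.0833). A difference in how the animals were handled before the nuclei were taken may lie behind the pattern and cannot be told apart from an effect of the genotype, as no label records the handling. With 2 WT samples, the genotype and an event in these samples remain open.

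Tnrc6b was lower in 6-month APP23 nuclei. The highest of the other libraries of the samples with high libraries, at 559 CPM, lay under the 776 CPM of the highest library of the remaining samples. This argues only against a difference shared by all libraries of a sample. The high libraries were picked as those over 1000 CPM, which by itself kept the others under that value. The high libraries exceeded the other libraries of the same samples over 2-fold in 4 of 4 classes, at 3978 against 448 CPM in dentate granule-like, 2397 against 548 CPM in CA1-like, 1806 against 521 CPM in CA2 or CA3-like and 2616 against 481 CPM in interneuron-like nuclei. As these libraries were picked by their Tnrc6b counts, this cannot decide for counts added in single libraries, and that explanation stays open. Of 10914 genes with 1000 or more counts, no gene but Tnrc6b had all 3 of these libraries above 2 times every other library.

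The 10 splits of 6 samples are too few for a share under 0.05. In both contrasts of APP23 with WT, the real counts of genes include human APP and Thy1 in each class. The lists called there include the transgene promoter and product. The genotype itself sets these calls, and the other splits mix the genotypes. A larger real count in these contrasts therefore says nothing about the other genes or lists. For counts of called genes, the real value and the highest of the other splits in dentate granule-like nuclei were 3 and 3 for genotype at 6 months (reached in 2 splits, the real one included), 4 and 4 for age in APP23 (2 splits) and 4 and 3 for 24-month APP23 against 6-month WT (1 split). In CA1-like nuclei they were 3 and 0 (1 split), 0 and 1 (10 splits) and 5 and 3 (1 split) for the same contrasts, and in CA2 or CA3-like nuclei 2 and 2 (2 splits), 0 and 3 (10 splits) and 5 and 5 (2 splits). In interneuron-like nuclei genotype at 6 months gave 2 and 1 (1 split). For called lists over the first 3 classes, adjusted over the 99 tests of a split and not over all 792 tests, they were 7 and 7 for genotype at 6 months (2 splits), 15 and 10 for age in APP23 (1 split) and 20 and 16 for 24-month APP23 against 6-month WT (1 split). The unadjusted camera p of the cholesterol list in CA1-like nuclei, with the smallest of the other splits beside it, was 1.75e-07 and 4.11e-05 for genotype at 6 months, 2.75e-11 and 3.21e-05 for age in APP23, and 3.72e-28 and 2.06e-08 for 24-month APP23 against 6-month WT, the real split having the smallest in each (1 split).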

How the results depend on the processing

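The settings that left out libraries or put sex in the model, and all settings applied to the gene lists apart from the other list tests and the replicate block, were chosen after seeing the data. The others were planned. With RLE factors, Leiden resolution 2, Scrublet doublets left out, nuclei of 2000 or more genes, or library 2 or 3 of 6-month APP23 replicate 1 left out, all 24 counts of called genes lay within 1.5 times the reported ones. No test of shares or depth changed its side of the threshold in any setting. Counts below run over the contrasts in the order genotype at 6 months, genotype at 24 months, age in WT, age in APP23, 24-month APP23 against 6-month WT, and the difference of the APP23 effect between the ages. The cause was not tested for any change given here.

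With no filter on low counts the numbers of called genes were 12, 16, 15, 14 and 5 in dentate granule-like nuclei from genotype at 24 months on. They were 17, 7, 44, 27 and 12 in CA1-like nuclei from genotype at 24 months on, 5, 7, 7, 16, 13 and 6 in CA2 or CA3-like nuclei, and 30, 8, 6, 1, 7 and 6 in interneuron-like nuclei. DESeq2, for all contrasts but the last, called 5, 10, 15, 19 and 23 dentate granule-like, 5, 8, 4, 32 and 27 CA1-like, 20, 5, 4, 14 and 13 CA2 or CA3-like, and, apart from age in APP23, 52, 6, 4 and 15 interneuron-like genes. Without the libraries low in Ttr the calls in dentate granule-like nuclei were 6 for genotype at 6 months, 2 for age in WT, 10 for age in APP23 and 4 for the difference between the ages. In CA1-like nuclei they were 2 for 24-month APP23 against 6-month WT and 1 for the difference, in CA2 or CA3-like nuclei 1 for the difference, and in interneuron-like nuclei 1 for genotype at 6 months. Without the libraries high in Tnrc6b they were 2 in dentate granule-like nuclei, both for age in APP23 and for 24-month APP23 against 6-month WT, and 3 in CA1-like nuclei for the latter. With sex in the model and library 3 of 6-month APP23 replicate 1 left out, CA2 or CA3-like nuclei had 3 for 24-month APP23 against 6-month WT.

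The replicate block, with the replicate number as a term, moved the calls for age in WT to 2 in dentate granule-like and 1 in CA1-like nuclei. It moved those for age in APP23 to 6 in CA2 or CA3-like nuclei, with Thy1 among them, and 1 in interneuron-like nuclei, and those for 24-month APP23 against 6-month WT to 4 in interneuron-like nuclei. It left 51 of the 62 called lists past the threshold and moved no other count by over 1.5 times. Correlations over genes gave no sign that the numbers pair the samples, but they cannot exclude it. The 15 pairs with the same number had correlations of deviations from −0.0853 to 0.103, with 1 over 0.1. Of the 11 samples, 5 correlated best with their own number. The libraries low in Ttr all belonged to replicate 1 of the 6-month groups, in WT and in APP23.

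Leaving out each sample in turn gave, with fewer samples in the fit, ranges in the order above of 2 to 3, 2 to 3, 0 to 2, 0 to 5, 2 to 5 and 0 to 1 in dentate granule-like nuclei and 2 to 3, 2 to 3, 0 to 1, 0 to 7, 2 to 8 and 0 to 1 in CA1-like nuclei. They were 2 to 3, 2 to 2, 0 to 0, 0 to 4, 2 to 5 and 0 to 0 in CA2 or CA3-like nuclei, and 2 to 3, 0 to 1, 0 to 1, 0 to 1, 1 to 3 and 0 to 1 in interneuron-like nuclei. Where this left a group with 1 sample, that sample was assumed to vary like the other groups. Some log2 values changed sign, none of them past the threshold. In dentate granule-like nuclei, without 24-month WT replicate 1, mouse App reached −0.0745 for age in WT (−0.0745 to 0.55 without each sample), 0.16 for genotype at 24 months (−0.47 to 0.16) and 0.30 for the difference between the ages (−0.32 to 0.30). Thy1 there reached 0.23 for age in WT (−0.34 to 0.23). Without 24-month APP23 replicate 1, Thy1 in interneuron-like nuclei reached −0.45 for age in APP23 (−0.45 to 0.33).

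Of the 62 lists called by camera, 1 passed with an estimated correlation and 4 passed with fry. A total of 25 held without each sample. Among these were calls of the transgene promoter and product, which the genotype itself sets where APP23 is compared with WT. Without the filter on low counts 46 held, and 47 held without the libraries low in Ttr. The number was 55 without those high in Tnrc6b, and 49 with sex in the model and library 3 of 6-month APP23 replicate 1 left out. In the simulated data, for genes above the median count, 2.99% of 2-fold changes between genotypes at 6 months were recovered in interneuron-like nuclei. In CA1-like nuclei 16.4% were.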

Other observations

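The lists and contrasts in this part were planned, and the fits of the lists without single samples and the values of single libraries were chosen after the results were seen.

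Several other gene groups passed in the planned list tests. Interferon response and antigen presentation genes were higher with age in CA1-like nuclei of APP23 for 12 of 13 members (median log2 fold change 0.98, camera adjusted p = 0.00530; adjusted p = 0.266 with an estimated correlation). That call was lost without 24-month APP23 replicate 1 (adjusted p = 0.196) or replicate 2 (0.0917). The 5 microglia markers were all higher in the same nuclei and contrast (adjusted p = 0.0117; 0.349 with an estimated correlation), a call that held without each sample. The unfolded protein response genes of the endoplasmic reticulum were lower in APP23 at 24 months in CA1-like nuclei for 17 of 23 members (median −0.32, adjusted p = 0.0410; 0.757 with an estimated correlation). Among them were Calr, a calcium-binding chaperone, at 199 ± 51.4 (SD, n = 3) against 370.2 ± 30.1 CPM (n = 2; −0.88, SE 0.27) and Hspa5, the main chaperone of that compartment, at 192 ± 112 against 393 ± 47.1 CPM (−0.998, SE 0.42), neither past the threshold over the list alone. The call was lost without 24-month WT replicate 1 (0.432), APP23 replicate 2 (0.0727) or APP23 replicate 3 (0.282).

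Genes of nuclear-encoded oxidative phosphorylation were lower in dentate granule-like nuclei of 6-month APP23 for 52 of 75 members (median −0.24, adjusted p = 0.0109; 0.892 with an estimated correlation), lost without 6-month WT replicate 2 (0.0849), WT replicate 3 (0.644) or APP23 replicate 1 (0.130). Axon guidance and adhesion genes were lower in CA1-like nuclei of 6-month APP23 for 35 of 48 members (median −0.20, adjusted p = 0.0126; 0.521 with an estimated correlation), lost without 6-month WT replicate 3 (0.0985), APP23 replicate 1 (0.0726) or APP23 replicate 3 (0.172). Ribosomal protein genes of CA2 or CA3-like nuclei were lower with age in APP23 for 59 of 78 members (median −0.30, adjusted p = 0.000680; 0.757 with an estimated correlation), lost without 6-month APP23 replicate 3 (0.210). Cholesterol synthesis genes were also higher in interneuron-like nuclei of 24-month APP23 against 6-month WT for 16 of 21 members (median 0.79, adjusted p = 0.00255; 0.588 with an estimated correlation), lost without 24-month APP23 replicate 2 (0.228).

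Prl, the pituitary hormone prolactin, was counted at 3.93 to 33.8 CPM in 6 of the libraries of 24-month WT and at 0 in library 4 of its replicate 2. It was also counted at 15.1 and 1.83 CPM in libraries 1 and 2 of 24-month APP23 replicate 1 and at 0.59 CPM in library 2 of 6-month WT replicate 3. Library 2 of 6-month APP23 replicate 1 had a median of 151660 counts per nucleus, the highest of the 36 libraries.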
